A study of Mus musculus with 69 samples.

How the data were processed

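Bulk RNA was measured in 69 libraries of mouse naive CD4 T cells cultured for 72 h with antibody to CD3 at 1 ug/ml and IL-27 at 25 ng/ml; the labels also name an antibody to CD8 at the same concentration. Per the labels, 2000 cells were lysed for each library and polyadenylated RNA was sequenced with an adaptation of SMART-Seq2. Deletion used Cre lines for Prdm1, Maf, both together, Atf3, Cebpb, Fosl2, Hif1a, Irf8, Nfil3 and Stat3, and the other factors are named as knockouts only. Irf9 cells were BALB/c and all others C57BL/6. The authors aligned reads with TopHat to mm9 and deposited, for each library, expected counts per gene estimated with RSEM, not scaled for depth; versions are not given in the sources used here. The tables hold 23366 genes by symbol, and 22.4% of nonzero expected counts are not whole. TPM and FPKM columns were not used here. Reads were not analysed here.

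Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3: filterByExpr on the design, TMM scaling, estimateDisp, glmQLFit and the quasi-likelihood F-test, with default settings. Adjusted p-values are Benjamini-Hochberg values over all genes tested in a comparison, with a threshold of 0.05. Each of the 12 experiments was fitted alone. The Prdm1, Maf and double knockouts shared a fit of 12 libraries with a mean per group, which also gave the interaction. Batf, Irf1, Irf8 and Stat3 shared a fit of 12 libraries with genotype and batch as terms, because their controls overlap; batches A and B follow the titles, and the remaining Irf1 control and 2 Irf1 knockout libraries were set as batch C by exclusion. Other experiments had a mean per group. The labels do not say that replicate numbers pair samples, so they were a block only as an alternative. Libraries of the same number deviated from their groups together in Hif1a (correlation 0.297) and Tbx21 (0.18) and opposite ways in Nfil3 (-0.261 and -0.35); in the other experiments outside the linked one the correlations lay from -0.0842 to 0.0982. Apart from the additions named below, the sets of libraries, tests, alternatives, gene lists and the naming rule were chosen before the data were examined. The tests on genes near Ahr, on sex in Ahr and on RNA from B cells and other cell types were chosen after results were seen.

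Genes were named by rule: the target; Il10; up to 8 rises and 8 falls with the largest log2 change among genes past the threshold, with a mean of at least 20 CPM in the higher group and every knockout library beyond every control library (within batches for linked comparisons); up to 4 members of each list past the threshold; and other knocked-out factors past the threshold. Predicted genes, ribosomal and small RNA genes, antigen receptor segments and sex genes were left out, and not every gene the rule allows is named; some genes, 1 of them with a library far from the others, are not reported here. Where a group was at 0 in all libraries, a fold is a lower bound against a floor of 3 counts per library. Such bounds and the counting intervals cover counting error only. Ratios within batches used a pseudocount of 0.5 CPM.

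There were 23 gene lists of 5 to 56 members: Tr1 markers, co-inhibitory and co-stimulatory receptors, cytokines and chemokines, interferon-stimulated genes, Th1, Th17, Th2, Treg and Tfh programmes, naive and memory genes, glycolysis and hypoxia, the aryl hydrocarbon receptor battery, cell cycle, STAT3 and IL-6 family targets, integrated stress and unfolded protein response, effector and cytotoxic genes, cholesterol and fatty acid synthesis, markers of B cells, of myeloid and dendritic cells, of CD8 T and NK cells and of erythroid cells and platelets, immediate early and heat shock genes, and sex genes. Lists with at least 3 tested members were tested against all other genes with camera in limma 3.58.1, with a preset correlation of 0.01 and with an estimated one, and adjusted over the lists of a comparison. Counts adjusted over the list alone use Benjamini-Hochberg values over its tested members. The test with an estimated correlation rests on at most the residual degrees of freedom of a fit. These were 2 in the experiments of 2 against 2 libraries, 5 in Irf9 and the linked fit, and 8 in the Prdm1 and Maf fit. A call lost where they are few does not show that a list did not move.

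Alternatives planned were DESeq2 size factors in edgeR, DESeq2 1.42.0, no filter on low counts, a replicate block, no batch term, only the libraries of a comparison's own batches, 1 fit over all 69 libraries, and leaving out each library in turn. Added after seeing the data were fits of the Prdm1 and Maf comparisons and list tests without replicate 3 of the double knockout, of the linked comparisons without Irf8_KO 1, list tests with the targeted gene left out of its lists, and fits of Irf4 and Irf9 with library pairs summed whose counts differed by a chi-square per degree of freedom under 1.3. Of 49 pairs of replicate libraries none was identical, and this ratio ran from 1.08 to 772. Other splits of the libraries were counted where both groups had at least 3 libraries. Genes near a target were found by symbol in a RefSeq table for GRCm38, which is not the build of the deposited values. Simulations of shared controls were run 20 times. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

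The test was run on simulated data with 200 genes changed by a log2 of 1 or 2 at the depth and spread of 14 comparisons. The changed genes were drawn from those with a mean of at least 10 CPM in the controls, so recovery at lower levels was not checked. Batch effects in the linked fits were drawn with a set spread that was not estimated from the data. At a log2 of 2 it recovered from 98 to 100% of changed genes in Prdm1 (11 libraries), Ahr, Atf3, Ets1, Hif1a, Irf4, Irf9, Nfil3 and Tbx21, from 84.1 to 85.6% in Batf, Irf1 and Irf8, 54% in Stat3 and 5.38% in Fosl2. At a log2 of 1 the shares were 71.2 to 100%, 23.2 to 27.1%, 7% and 0%. False calls made up 5.37% of 2179 calls, under the limit of 10%. That limit over all comparisons replaced a limit for each comparison after Fosl2, with 4 false calls of 9, had exceeded it; Tbx21 had 25 of 203. Cebpb, with 765 genes tested, Maf and the double knockout were not part of this check. Prdm1 was checked only in the fit of 11 libraries, with a common coefficient of variation of 0.0678. In the main fit of 12 libraries it was 0.495, so the recovery for Prdm1 does not apply to that fit.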

Results

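The series measured polyadenylated RNA in mouse CD4 T cells stimulated for 72 h with antibody to CD3 and with IL-27, a cytokine that drives naive cells toward type 1 regulatory (Tr1) cells, which secrete IL-10. The 69 libraries came from 2000 lysed cells each and fall into 12 experiments, each with its own controls. By their labels, the cells lacked 1 of 16 transcription factors, or both Prdm1 and Maf, which gives 17 knockout comparisons; the series title names regulators of IL-10 expression as the subject. The Prdm1 knockout, the Maf knockout, the double knockout and their shared control had 3 libraries each. The Ahr, Atf3, Cebpb, Ets1, Fosl2, Hif1a and Tbx21 experiments compared 2 knockout with 2 control libraries, Irf4 and Nfil3 compared 2 with 3, and Irf9 compared 4 with 3. Batf (2 libraries), Irf1 (3), Irf8 (2) and Stat3 (1) shared 4 control libraries across 3 batches, A, B and C, given by the titles and, for C, by exclusion.

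Library totals ranged from 743427 to 15221863 counts, with 9120 to 13880 genes detected, in 64 libraries. The other libraries were the 4 of Cebpb, with 30593 to 46232 counts, and replicate 3 of the double knockout, with 9056 counts in 176 genes. Per experiment, totals ranged from 2005572 to 3365474 counts for Ahr, from 1983879 to 2264519 for Atf3, from 4266053 to 4690256 for Ets1 and from 2052307 to 3458636 for Hif1a. They ranged from 1056235 to 4149265 for Irf4, from 996603 to 1688568 for Irf9, from 1946766 to 2425233 for Nfil3 and from 4454233 to 4863111 for Tbx21. Totals ran from 743427 to 4564163 in the 12 linked libraries of Batf, Irf1, Irf8 and Stat3, and from 3888525 to 15221863 in Fosl2. Ribosomal Rn45s held 84.8% of the counts of Fosl2_KO 1 and 43.7% of those of Irf8_KO 1. Changes below are log2 fold changes, knockout-labelled against control, with the standard error (SE) of the fit after ±, and levels are mean CPM, counts scaled to a common library size. For gene lists, counts in parentheses are adjusted over the list alone, followed by the adjusted p of the camera test with a preset correlation and by that with an estimated correlation. Genes named for the size of their change had a mean of at least 20 CPM in the higher group. They also lay beyond every control library in every knockout library, within batches where there were any. Where genes are said to rise or fall most, the ranking is among these genes only. Members named for a gene list were not held to this, and some of them changed more. Nothing in the labels says that replicates came from separate animals or cultures, so p-values measure the spread between these libraries. In the 12-library fit of Prdm1 and Maf the quasi-likelihood part of that spread was fully pooled over genes.

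The targeted gene was lower in 6 of the 15 comparisons of a single factor in which it could be tested: Prdm1 (-2.98 ± 0.30), Batf (-6.28 ± 0.57), Stat3 (-5.21 ± 0.45), Tbx21 (-2.33 ± 0.18), Irf4 (-1.15 ± 0.09) and Maf. Maf had 0 counts in all 3 Maf knockout libraries, which makes it at least 145-fold lower against a floor of 3 counts per library. It did not pass the threshold in 8: Irf9 (-0.61 ± 0.20, adjusted p = 0.0791), Irf1 (-0.67 ± 0.23, 0.436), Hif1a (-0.32 ± 0.18, 0.442) and Nfil3 (-1.38 ± 0.75, 1) with negative values. Positive values were those of Irf8 (0.12 ± 0.23, 0.978), Ets1 (0.20 ± 0.07, 0.0517), Ahr (0.87 ± 0.33, 0.529) and Fosl2 (1.00 ± 0.64, 0.933). Nfil3 had 429 counts in Nfil3_KO 1 and 6 in Nfil3_KO 2, so these libraries did not lose the transcript alike. Atf3 was higher in the libraries labelled Atf3 knockout (1.94 ± 0.19, adjusted p = 8.42e-10), and Cebpb had too few counts to be tested. Gene totals cannot show a deleted exon or a lost protein, so the knockout names below follow the labels.

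**Figure D1:**
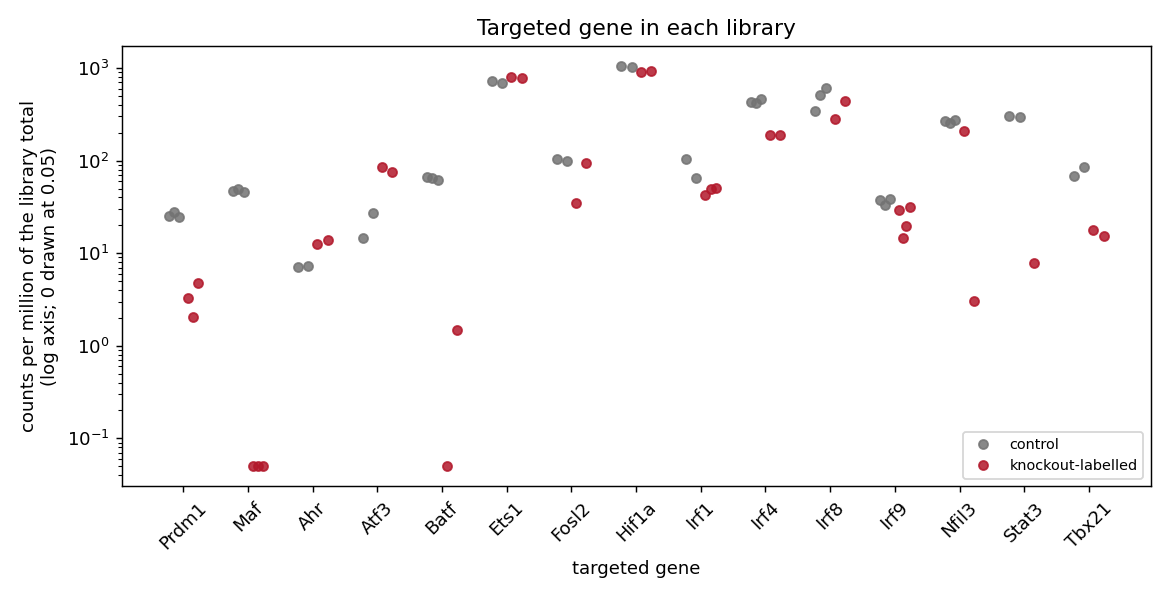
CPM of the library total (log axis, 0 drawn at 0.05) of the targeted gene in each control library (grey) and each knockout-labelled library (red), for 15 factors. Maf was at 0 in its 3 knockout libraries, and Atf3 was higher in both libraries labelled Atf3 knockout than in both controls.

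Il10, the cytokine gene named in the series title, fell in 8 and rose in 3 of the 16 comparisons in which it was tested. It fell most in the double knockout (-6.38 ± 0.48, adjusted p = 3.48e-37) and the Prdm1 knockout (-5.69 ± 0.39, 4.7e-43). Next came Stat3 (-3.98 ± 0.65, 0.00487; 1 knockout library), Maf (-3.18 ± 0.33, 5e-19) and Batf (-3.06 ± 0.42, 0.000484). Smaller falls were found for Irf1 (-2.68 ± 0.40, 0.00421), Hif1a (-1.48 ± 0.23, 0.00174) and Atf3 (-0.76 ± 0.14, 0.000148). Il10 rose in Irf4 (3.21 ± 0.24, 2.2e-10), Ets1 (1.99 ± 0.11, 8.42e-07) and Irf9 (0.84 ± 0.17, 0.002). The levels were 38.0 against 3.83 CPM in Irf4, 124.5 against 31.3 in Ets1 and 45.7 against 25.5 in Irf9. In the Irf4 controls 3 counts are 0.723 to 2.84 CPM of the library total, so the size of that rise rests on a low control level. Adjusted over the list alone, that is over these comparisons, it fell in 9 and rose in 3. The added one was Tbx21 (-1.81 ± 0.59, 0.103 over all genes and 0.0203 over the list). Over all genes, Tbx21 passed with a replicate block (-1.94, adjusted p = 0.000997), no filter (0.0295) and 1 fit over all 69 libraries (0.0115). With DESeq2 it did not (0.486). The values for Fosl2 (-1.50 ± 0.99, 0.933), Irf8 (0.56 ± 0.35, 0.949), Nfil3 (-0.18 ± 0.22, 1) and Cebpb (-0.14 ± 1.14, 0.994) did not pass. In Nfil3, Il10 changed by -0.65 without Nfil3_KO 1, the knockout library with more Nfil3 counts, and by 0.17 without Nfil3_KO 2. In Ahr, Il10 had too few counts to be tested, with 3 and 4 counts in the knockout and 29 and 7 in the control libraries. The calls for Atf3, Hif1a and Irf9 ended in a fit over all 69 libraries, with changes of -0.75, -1.50 and 0.84, and that for Atf3 also with DESeq2. The call for Maf ended with no filter on low counts (-3.18, adjusted p = 1), with a replicate block (-3.17, 0.4) and without any 1 Maf knockout library, that for Stat3 without the batch term (-3.47, 0.0628), and that for Irf1 with the libraries of its own batches (-2.71, 0.0923) or without Irf1_Ctrl 2 (-2.14, 1). The fits in which Maf lost its call all kept replicate 3 of the double knockout, the library of 9056 counts. Without that library Il10 in Maf passed (-3.18, adjusted p = 6.62e-13). In Prdm1, Il10 passed without Prdm1_KO 1, 2 or 3, but with adjusted p of 0.00618, 0.00981 and 0.0275. In the double knockout it passed without replicates 1 and 2 (0.00171 and 0.000734). The far smaller values of the main fit rest on a spread pooled over genes. The fall in Atf3 follows the labels, although Atf3 itself was higher in the libraries labelled knockout. Whether these labels are swapped was not tested, and with that direction turned the counts would be 7 falls and 4 rises.

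**Figure D2:**
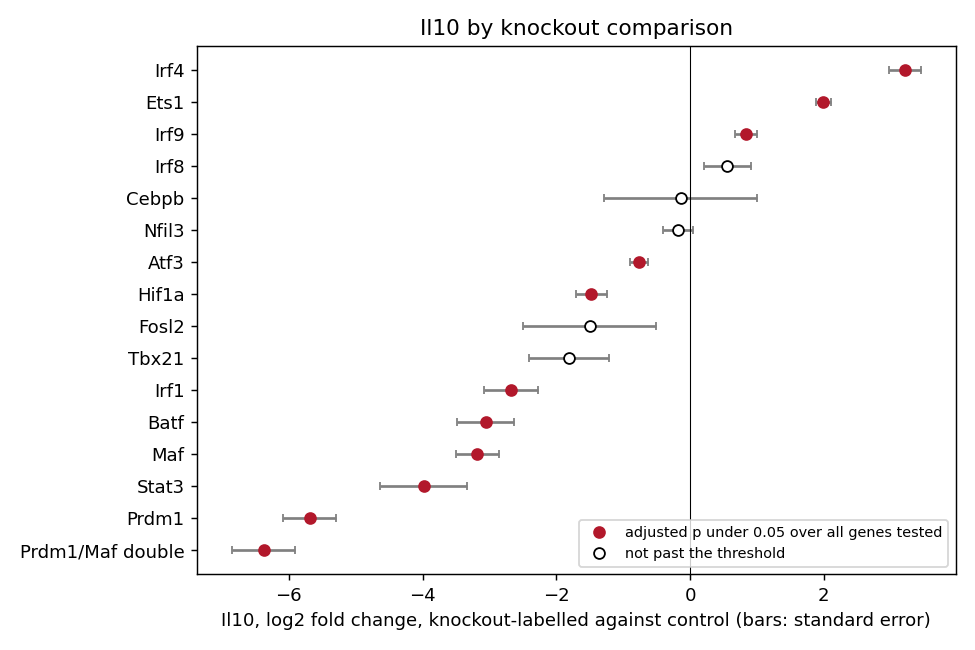
Log2 fold change of Il10, knockout-labelled against control, in the 16 comparisons that could test it; bars are standard errors and filled points passed an adjusted p of 0.05 over all genes tested. Values run from -6.38 in the double knockout to 3.21 in Irf4.

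Prdm1 encodes Blimp-1, a transcriptional repressor of effector lymphocytes, and Il10 and 4 other Tr1 markers, Prdm1 itself among them, fell in its knockout. Beside Il10, the genes that fell most were Emp1 (-2.36 ± 0.27), the chemokine receptor Ccr1 (-2.07 ± 0.28), the protease-activated receptor F2rl2 (-2.01 ± 0.28), the ectonucleotidase Entpd1 (-1.76 ± 0.26), Pyhin1 (-1.54 ± 0.27), the metalloprotease Adam8 (-1.31 ± 0.27) and the kinase Sgk1 (-1.26 ± 0.26). Those that rose most were the protease Prss16 (1.75 ± 0.29), Tuba8 (1.64 ± 0.30), the T cell receptor adaptor Tespa1 (1.42 ± 0.27), Bst1 (1.33 ± 0.27), the hexose transporter Slc2a6 (1.21 ± 0.26), Synpo (1.13 ± 0.26) and Marcksl1 (1.11 ± 0.27). Of 19 tested Tr1 markers, 5 fell, Havcr2 (-3.86 ± 0.56) and Maf (-0.97 ± 0.24, adjusted p = 0.0113) among them, and none rose, with the same counts adjusted over the list alone. The camera adjusted p was 3.99e-26, and adjusted p = 0.0408 with an estimated correlation. Without Prdm1, whose change the deletion brings, 4 of 18 fell (4.74e-16, and adjusted p = 0.099 with an estimated correlation). The chemokine gene Xcl1 rose (1.43 ± 0.31), Isg20 (-1.33 ± 0.33) and Il1r1 (-1.48 ± 0.38) fell and Dapl1 rose (2.03 ± 0.50). Of 8 tested B cell markers, 6 rose (6 adjusted over the list alone; camera adjusted p = 4.44e-20, and adjusted p = 0.00972 with an estimated correlation), with Cd79a at 4.94 against 0.654 CPM. Cd8a rose (5.42 ± 0.58) from 0.176 to 7.94 CPM, a level below the 20 CPM limit of the ranking above. In all, 83 of 11132 tested genes passed, 44 up and 39 down. Without the double knockout's replicate 3, a library in the same fit, 1367 passed (562 up, 805 down; 78 shared), among them Lif (1.21 ± 0.08), Tcf7 (1.02 ± 0.08), Igfbp4 (1.15 ± 0.07) and Ccl5 (-1.76 ± 0.06). Counts fell to 37, 45 and 38 without control replicates 1, 2 and 3, to 49, 50 and 40 without Prdm1_KO replicates 1, 2 and 3, and to 33 with DESeq2.

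Maf encodes c-Maf, a transcription factor of IL-10-producing T cells, and Il10 and 3 other Tr1 markers, Maf itself among them, fell in its knockout. The largest falls after Il10 were those of Emp1 (-2.51 ± 0.28), the serpin Serpina3f (-2.24 ± 0.36), Podnl1 (-1.77 ± 0.29), F2rl2 (-1.60 ± 0.27), podoplanin Pdpn (-1.54 ± 0.27), the leukotriene receptor Cysltr1 (-1.50 ± 0.30) and the proprotein convertase Furin (-1.50 ± 0.32). The largest rises were those of proenkephalin Penk (1.98 ± 0.34), the mitochondrial transhydrogenase Nnt (1.60 ± 0.37), Bst1 (1.21 ± 0.28), Pltp (1.18 ± 0.28), Pls1 (1.14 ± 0.27), granzyme gene Gzma (1.11 ± 0.28), Eml2 (1.11 ± 0.27) and M1ap (0.99 ± 0.26). Nnt stayed near the shared controls in replicates 1 and 2 of the double knockout (20 and 18.7 CPM of the library total). Its rise was thus not shared by both groups that lack Maf. Of 19 tested Tr1 markers, 4 fell, Prdm1 (-0.97 ± 0.25, adjusted p = 0.0277) and Entpd1 (-0.92 ± 0.25) among them, and none rose, with the same counts adjusted over the list alone (camera adjusted p = 3.64e-21, and adjusted p = 0.0682 with an estimated correlation). Maf itself, at 0 counts in the 3 knockout libraries, is a member, and without it 3 of 18 fell (6.32e-07, and adjusted p = 0.534 with an estimated correlation). Among 23 cytokine genes, Il10, Il4 (-1.99 ± 0.44) and Csf1 (-1.79 ± 0.32) fell and Xcl1 rose (1.56 ± 0.31), or 5 down and 1 up adjusted over the list alone (3.52e-05, and adjusted p = 0.802 with an estimated correlation). In all, 64 genes passed, 27 up and 37 down; without the double knockout's replicate 3, 1021 passed (445 up, 576 down; 56 shared), with Il21 at -1.05 ± 0.07 and Dclk1 at 1.36 ± 0.11. In the 12-library fit 27, 29 and 25 passed without control replicates 1, 2 and 3. Without Maf_KO replicates 1, 2 and 3 the counts were 24, 27 and 20. There Il10 kept changes of -3.13, -3.16 and -3.25 but lost its call. Without replicate 3 of the double knockout Il10 kept its call (-3.18 ± 0.13, adjusted p = 6.62e-13).

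In the double knockout, Emp1, F2rl2 and Entpd1 fell, as they did in both single knockouts. Beside Il10, the genes that fell most were Emp1 (-4.63 ± 0.39), F2rl2 (-2.65 ± 0.33), Entpd1 (-2.35 ± 0.30), Ccr1 (-2.27 ± 0.31), Pdpn (-2.27 ± 0.31), Furin (-1.91 ± 0.35) and Adam8 (-1.70 ± 0.30), against a median change of all genes of -0.30 in this fit. List members that fell were Il4 (-5.46 ± 0.77), Ccl20 (-3.74 ± 0.85), Havcr2 (-3.24 ± 0.57), Il1r1 (-2.90 ± 0.51) and Gpr83 (-1.23 ± 0.35), and Xcl1 (3.19 ± 0.30) rose. Of 19 tested Tr1 markers, 5 fell and 1 rose, the same adjusted over the list alone (camera adjusted p = 1.71e-21, and adjusted p = 0.00276 with an estimated correlation). Without Prdm1 and Maf, 3 of 17 fell and 1 rose (8.34e-08, and adjusted p = 0.14 with an estimated correlation). Among 8 B cell markers, 6 rose (6 adjusted over the list alone; 4.37e-17, and adjusted p = 0.0281 with an estimated correlation). Cd79a (2.71 ± 0.51) was among them. The Th1 list was called up (0.0278) while its median (-0.69) and mean (-0.20) were negative, and the call was lost with an estimated correlation (adjusted p = 0.957). The named rises Il18r1 (6.19 ± 0.81), Tmem151b (3.11 ± 0.50), Slc38a6 (1.60 ± 0.44) and Gga2 (1.57 ± 0.37) rested on replicate 3, the library of 9056 counts. Without it they were 1.01 ± 0.40, 1.02 ± 0.49, 0.87 ± 0.38 and 0.72 ± 0.27 and none passed. In all, 166 genes passed, 89 up and 77 down. Without replicate 3, 2150 passed (928 up, 1222 down; 146 shared) with a median change of 0.01. Its largest rises were Xcl1 (3.35 ± 0.18), Penk (1.81 ± 0.13), Serpinb9b (1.74 ± 0.17), Tespa1 (1.67 ± 0.12), Bst1 (1.65 ± 0.19) and Crtam (1.62 ± 0.12). Counts were 53 and 61 without replicates 1 and 2, and 76, 81 and 77 without control replicates 1, 2 and 3. In that 11-library fit, Il10 stood at 86.2 CPM in the controls, 1.70 in Prdm1, 9.46 in Maf and 1.06 in double knockouts.

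Whether the double knockout differed from the sum of the single knockouts was tested as an interaction. It passed for 23 genes (13 up, 10 down), of which the naming rule keeps Il18r1 (5.87 ± 1.05), whose value was 0.69 ± 0.57 without replicate 3 of the double knockout. Without that library 124 genes passed (63 up, 61 down; 7 shared with the 23). Il10 was among them (2.53 ± 0.47, adjusted p = 0.00702): its fall in the double knockout (-6.35 ± 0.22) was smaller than the sum of those in Prdm1 (-5.70 ± 0.17) and Maf (-3.18 ± 0.13). Il10 was already at 1.70 CPM in Prdm1 and 1.06 in double knockout libraries, where 3 counts are 0.268 and 0.3 CPM of the library total. With so little room for a further fall, a floor of the measured level and an interaction cannot be told apart for Il10. Serinc3 (1.16 ± 0.10), Ankrd37 (1.04 ± 0.22) and Serpinb9b (1.00 ± 0.24) had the largest positive and Arpc3 (-1.09 ± 0.16), Ifitm3 (-0.82 ± 0.17) and Asb2 (-0.65 ± 0.11) the largest negative terms under the rule. Counts were 15 without control replicate 1 or 2, 13 without Prdm1_KO 1, 12 without Maf_KO 1 and 9 without Maf_KO 3.

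Batf is an AP-1 family factor, and its knockout lowered genes of glycolysis and of the Tr1 programme. Of 36 tested genes of glycolysis and hypoxia, 31 fell and none rose (33 and none adjusted over the list alone; camera adjusted p = 4.98e-55, and adjusted p = 0.0039 with an estimated correlation). Ndrg1 changed by -3.10 ± 0.27, Aldoc by -2.95 ± 0.24, the glucose transporter Slc2a3 by -2.82 ± 0.26 and Bnip3 by -2.73 ± 0.27. Of 18 Tr1 markers, 7 fell and 1, Cd226 (2.10 ± 0.42), rose (10 and 2 adjusted over the list alone; 1.28e-07, and adjusted p = 0.0267 with an estimated correlation). Maf fell by 5.66 ± 0.72 and Entpd1 by 3.01 ± 0.67. Of 22 STAT3 and IL-6 family targets, 9 fell (11 adjusted over the list alone; 1.28e-13, and adjusted p = 0.0039 with an estimated correlation), or 8 of 21 without Batf (10; 3.06e-10, and adjusted p = 0.00797 with an estimated correlation). Of 12 effector genes, 6 fell and 2 rose (6 and 2; 6.74e-06, and adjusted p = 0.0435 with an estimated correlation). Klrc1 changed by -4.72 ± 0.59 and perforin Prf1 by -2.62 ± 0.35. The largest other falls were Ctla2a (-6.55 ± 0.54), Il24 (-5.28 ± 0.80), Dntt (-4.90 ± 0.48), Itga7 (-4.84 ± 0.45), Serpinb5 (-4.71 ± 0.36) and Sema4f (-4.46 ± 0.28). Rises were led by Oas1a (6.30 ± 0.81), the interleukin-1 receptor antagonist Il1rn (5.60 ± 0.60), Pkib (4.62 ± 0.82), Lad1 (4.32 ± 0.53), Cd70 (4.31 ± 0.56), interleukin-2 gene Il2 (3.97 ± 0.29), Spib (3.32 ± 0.80) and Stra6 (3.27 ± 0.54). Nfil3 (-2.16 ± 0.30), Hif1a (-1.25 ± 0.32), Fosl2 (-1.12 ± 0.21) and Ets1 (-1.08 ± 0.24) also fell, and Irf8 rose (0.95 ± 0.22). Hif1a lies among the 200 tested genes nearest Batf, so linkage and regulation cannot be told apart for its fall. Log2 ratios within batches A and B were -2.66 and -3.07 for Il10, -2.47 and -3.03 for Slc2a3 and 4.38 and 3.43 for Il2. In all, 447 genes passed, 128 up and 319 down. Of other settings, 118 and 160 passed without Batf_KO 1 and 2, and 233 without LinkedA_Ctrl 1.

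Hif1a encodes the oxygen-regulated subunit of hypoxia-inducible factor 1, and 35 of 36 tested genes of glycolysis and hypoxia fell in its knockout (36 adjusted over the list alone; camera adjusted p = 7.24e-147, and adjusted p = 0.0302 with an estimated correlation). Slc2a3 fell from 1076 to 38.7 CPM (-4.80 ± 0.22), Bnip3 by 4.69 ± 0.26, Aldoc by 3.95 ± 0.32 and P4ha2 by 3.56 ± 0.33. Other large falls were Mgarp (-5.70 ± 0.50), Dntt (-5.08 ± 0.47), Itga7 (-4.89 ± 0.33), the alarmin Il33 (-4.67 ± 0.37), Il24 (-4.40 ± 0.49), transglutaminase Tgm2 (-4.39 ± 0.24), Vldlr (-4.31 ± 0.40) and Tgfb3 (-4.19 ± 0.28). Of 15 Tr1 markers, 8 fell and none rose, the same adjusted over the list alone (2.3e-05, and adjusted p = 0.201 with an estimated correlation). Entpd1 (-2.14 ± 0.49), Prdm1 (-1.44 ± 0.37) and Gzmb (-1.24 ± 0.20) were among them. Of 14 Treg genes, 7 fell (9 adjusted over the list alone; 1.05e-07, and adjusted p = 0.201 with an estimated correlation), with Lrrc32 at -2.68 ± 0.31 and Ctla4 at -1.28 ± 0.23. Ifng (-1.54 ± 0.19) and Nfil3 (-1.76 ± 0.18) fell too. Of 10 tested B cell markers, 9 rose and 1, H2-Ab1, fell (9 and 1 adjusted over the list alone; 4.59e-26, and adjusted p = 0.201 with an estimated correlation). Those that rose included H2-Aa (3.37 ± 0.32) and Cd74 (2.89 ± 0.25, 205 against 27.9 CPM). With these rose Syk (3.86 ± 0.36), Cd22 (3.22 ± 0.45), Cxcr5 (2.39 ± 0.42) and Pou2af1 (1.47 ± 0.20), while Cd8a rose to 6.3 from 0.687 CPM (3.02 ± 0.60). Btg3 was at 0 in both controls and at least 27.6-fold higher. In all, 549 genes passed, 135 up and 414 down. Of other settings, 331 passed with DESeq2, 143 in the fit over all libraries, 1247 and 1429 without Hif1a_KO 1 and 2, and 301 and 347 without Hif1a_Ctrl 1 and 2.

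**Figure D3:**
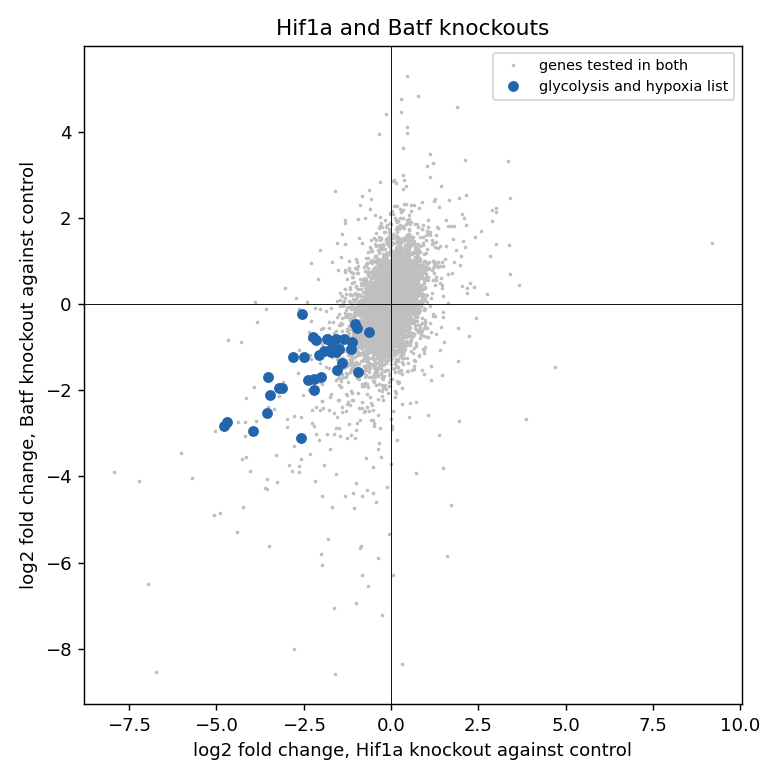
Log2 fold change of each gene tested in both the Hif1a (horizontal) and the Batf (vertical) comparison, with the 36 genes of the glycolysis and hypoxia list in blue. The blue points lie at negative values on both axes, down to -4.80 for Hif1a and -3.10 for Batf.

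Stat3 transmits the IL-27 signal, and its single knockout library was compared with 2 batch B controls in a fit that takes the spread from the other groups, so that a change in this 1 library and an effect of the deletion cannot be separated. Of 22 STAT3 and IL-6 family targets, 7 fell and none rose (12 and none adjusted over the list alone; camera adjusted p = 8.83e-13, and adjusted p = 0.0141 with an estimated correlation). Il21 changed by -5.75 ± 0.92, Tnfrsf8 by -3.44 ± 0.75 and Fosl2 by -3.36 ± 0.36. Of 18 Tr1 markers, 4 fell (10 down and 2 up adjusted over the list alone; 1.53e-06, and adjusted p = 0.0438 with an estimated correlation). Lag3 (-1.76 ± 0.31) was among them. Several genes were at 0 in the knockout library and so at least 58.3-fold lower for Timp1, 28.8-fold for Serpinb5, 22-fold for Il13ra1, 17.8-fold for Lrp1, 13-fold for C3, 12-fold for Tgm1 and 11.8-fold for Hlx. Sema4f (-6.49 ± 0.53), Tgfb3 (-5.30 ± 0.97), Igfbp4 (-4.29 ± 0.35) and Prf1 (-3.58 ± 0.56) fell as well. Of 36 glycolysis genes, 7 fell (14 adjusted over the list alone; 8.22e-11, and adjusted p = 0.0654 with an estimated correlation). Rises were led by Idi2 (5.08 ± 1.09), Lad1 (4.49 ± 0.62), Pkib (4.42 ± 0.97), Tbc1d4 (4.41 ± 0.94), the Th2 regulator Gata3 (3.74 ± 0.73), Cd83 (3.43 ± 0.53), Il2 (3.21 ± 0.35) and Ifng (2.11 ± 0.27). Tgtp1, at 0 in the controls, was at least 98.4-fold higher. In all, 179 genes passed, 44 up and 135 down, with the single knockout library assumed to vary like the other groups of its fit; 109 passed without LinkedB_Ctrl 1 and 299 with DESeq2.

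Irf1, an interferon regulatory factor, is known to activate genes of the interferon response, and these fell in its 3 knockout libraries. Of 46 tested interferon-stimulated genes, 14 fell and none rose (22 and none adjusted over the list alone; camera adjusted p = 5.4e-48, and adjusted p = 0.000667 with an estimated correlation). These included Iigp1 (-6.23 ± 0.56), the guanylate-binding protein genes Gbp2 (-3.90 ± 0.26) and Gbp6 (-2.97 ± 0.36), Zbp1 (-3.60 ± 0.58) and Usp18 (-3.14 ± 0.56). Of 20 Th1 genes, 3 fell (7 adjusted over the list alone; 4.61e-13, and adjusted p = 0.00997 with an estimated correlation), Ccl3 (-2.38 ± 0.30) and Ifng (-2.10 ± 0.26) among them. Of 12 effector genes, Prf1 (-2.06 ± 0.31), Serpinb9 (-2.04 ± 0.26) and Klrk1 (-1.93 ± 0.30) fell (4 adjusted over the list alone; 9.18e-12, and adjusted p = 0.00997 with an estimated correlation). Osteopontin gene Spp1 (-3.78 ± 0.29), Il13ra1 (-3.34 ± 0.47), Ifi27l1 (-3.23 ± 0.45) and Ptpn14 (-2.81 ± 0.53) fell too. Tgtp2 fell by 6.67 ± 0.74. Named rises were Stra6 (3.58 ± 0.62), Wdfy1 (3.38 ± 0.53) and Klk8 (1.31 ± 0.24). Log2 ratios within batches A and C were -2.10 and -2.76 for Il10 and -4.65 and -3.63 for Gbp2. In all, 53 genes passed, 5 up and 48 down. Of other settings, 101 passed with DESeq2, 13 within its own batches alone, 18 without Irf1_KO 1 and 2 without Irf1_Ctrl 2, where Il10 kept a change of -2.14 but not its call.

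Irf8 knockout libraries differed from controls in 5 genes, 4 up and 1 down. These were Emp1 (2.80 ± 0.37), Hemk1 (1.79 ± 0.27), the predicted gene Gm5779 (3.69 ± 0.42, named after its value was seen), Tgtp1 and Cd74. Tgtp1 was at 0 in the controls and at least 23.7-fold higher, and the invariant chain gene Cd74 fell by 3.30 ± 0.43. Log2 ratios within batches A and B were -3.81 and -2.94 for Cd74. No member of the Th1, Treg, glycolysis or effector lists passed over all genes (2 effector genes fell adjusted over the list alone). Camera called the Th1 (median -0.35) and effector (-0.67) lists down and the Treg (0.28) and glycolysis (0.17) lists up. The adjusted p ran from 0.0154 to 0.0282, and from 0.261 to 0.386 with an estimated correlation. None of the 5 genes passed without Irf8_KO 1, 3 passed without LinkedA_Ctrl 1, 11 without Irf8_KO 2 (1 shared) and 22 with DESeq2.

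Irf4, an interferon regulatory factor that binds DNA with AP-1 factors, had 2934 changed genes, 1553 up and 1381 down, the largest count among the fits by experiment; in the fit over all 69 libraries its 307 were fewer than the 494 of Batf and the 351 of Fosl2. All 9 tested Th2 genes rose (9 adjusted over the list alone; camera adjusted p = 1.29e-41, and adjusted p = 0.0672 with an estimated correlation). Il13 and Il5 were at 0 in the 3 controls and at least 7.21-fold and 2.85-fold higher, Il24 rose by 7.05 ± 0.17 and Epas1 by 4.50 ± 0.19. Of 24 cytokine genes, 19 rose and 4 fell, the same adjusted over the list alone (4.92e-21, and adjusted p = 0.0672 with an estimated correlation). Il22 changed by 7.46 ± 0.51 and Ifng by 2.67 ± 0.13. Of 14 Treg genes, 11 rose (12 adjusted over the list alone; 3.64e-25, and adjusted p = 0.0264 with an estimated correlation). Lrrc32 (3.51 ± 0.12), Nrp1 (3.48 ± 0.26) and Ctla4 (1.71 ± 0.09) were among them. Of 13 effector genes, 9 rose and 1 fell (9 and 2; 8.04e-19, and adjusted p = 0.0264 with an estimated correlation). Gzma changed by 7.42 ± 0.23 and Prf1 by 2.18 ± 0.09. Cell cycle genes fell, 24 of 32 (28 adjusted over the list alone; 1.44e-12, and adjusted p = 0.071 with an estimated correlation). Of 14 Tfh genes, 9 fell and 2 rose, the same adjusted over the list alone (2.57e-07, and adjusted p = 0.071 with an estimated correlation). Among the largest rises, Efna5, Pdk4 and Tgtp1 were at 0 in the controls and at least 68.6-fold, 13.2-fold and 24.1-fold higher. Adcy5 rose by 5.98 ± 0.31, Penk by 5.96 ± 0.13, Havcr2 by 4.79 ± 0.35 and the T-box gene Eomes by 4.01 ± 0.30. The largest falls were the pseudogene Pisd-ps3 (at least 86.3-fold), the sphingosine receptor S1pr1 (-4.21 ± 0.24), Plxnc1 (-3.88 ± 0.19), Il3 (-3.60 ± 0.41), Id3 (-3.60 ± 0.35), St8sia4 (-3.59 ± 0.26), Lsp1 (-3.45 ± 0.16), Pls1 (-3.27 ± 0.31) and Chst2 (-3.12 ± 0.21). The libraries also parted by sex, with Xist at 1.65 against 398 CPM and Ddx3y at 31 against 0, and by Nnt (1.16 ± 0.18). Control replicates 1 and 2 differed by little more than sampling noise; 1462 genes passed with DESeq2, and 1707 and 1862 without Irf4_KO 1 and 2.

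Libraries labelled Ets1 knockout, for a factor of the ETS family, had higher Il10 and other Tr1 genes. Of 18 Tr1 markers, 11 rose and 4 fell, the same adjusted over the list alone (camera adjusted p = 1.77e-06, and adjusted p = 0.244 with an estimated correlation). Havcr2 changed by 3.23 ± 0.54, Prdm1 by 1.42 ± 0.14 and Maf by 1.27 ± 0.10. Of 9 Th2 genes, 8 rose (8 adjusted over the list alone; 1.77e-18, and adjusted p = 0.193 with an estimated correlation). Il24 changed by 2.88 ± 0.13 and Ccr8 by 2.06 ± 0.25. Of 11 Th17 genes, 7 rose and 1 fell (7 and 1; 6.95e-06, and adjusted p = 0.207 with an estimated correlation). Il22 (6.94 ± 0.28), Il17a (3.54 ± 0.75) and Il1r1 (3.14 ± 0.31) were among them. Of 15 Treg genes, 10 rose and 2 fell (10 and 4; 7.02e-08, and adjusted p = 0.193 with an estimated correlation). Ikzf2 changed by 2.29 ± 0.11 and Foxp3 by 1.96 ± 0.27. Cholesterol and fatty acid synthesis rose in 17 of 24 genes (18; 8.27e-09, and adjusted p = 0.244 with an estimated correlation), the desaturase Scd1 (1.27 ± 0.09) among them. Of 13 effector genes, 8 fell and 3 rose (8 and 3; 0.000907, and adjusted p = 0.387 with an estimated correlation). Ctsw changed by -2.57 ± 0.17 and Gzma by 3.86 ± 0.17. Other large rises were Dsg2 and Gdpd3, at 0 in the controls and at least 46.7-fold and 34.5-fold higher, Wdfy4 (5.57 ± 0.25), Fam177a (5.23 ± 0.65), Tns4 (5.04 ± 0.21), Ifitm1 (4.71 ± 0.22) and Myo1f (4.01 ± 0.24). Falls were led by the growth factor gene Pdgfb (-3.43 ± 0.22), Il3 (-3.24 ± 0.39), Bcl2a1b (-2.87 ± 0.16), H2-Oa (-2.68 ± 0.25), Pglyrp1 (-2.65 ± 0.25), Gmfg (-2.61 ± 0.14), Acvrl1 (-2.52 ± 0.14) and the glucose transporter Slc2a3 (-1.61 ± 0.07). In all, 2199 genes passed, 1083 up and 1116 down, with Xist at 1.43 against 122 CPM and Ddx3y at 35.1 against 0.118; 1150 passed with DESeq2 and 199 in the fit over all libraries.

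Irf9 acts in the type I interferon response, and its knockout, in BALB/c cells, lowered interferon-stimulated genes and raised Treg and Tr1 genes. Of 35 interferon-stimulated genes, 11 fell and none rose (12 and none adjusted over the list alone; camera adjusted p = 7.77e-10, and adjusted p = 0.00965 with an estimated correlation). Ifi27l2a changed by -2.24 ± 0.17, Oas3 by -1.58 ± 0.27, Lgals3bp by -1.11 ± 0.12 and Ifih1 by -0.75 ± 0.17. Of 13 Treg genes, 10 rose and none fell (12 and none; 6.61e-36, and adjusted p = 0.00444 with an estimated correlation). The Treg regulator Foxp3 changed by 1.75 ± 0.12, Ikzf2 by 1.67 ± 0.21, Lrrc32 by 1.58 ± 0.19 and Gpr83 by 1.13 ± 0.12. Of 14 Tr1 markers, 7 rose (10 up and 2 down adjusted over the list alone; 9.7e-08, and adjusted p = 0.0176 with an estimated correlation). Ahr (1.47 ± 0.40), Prdm1 (1.11 ± 0.15) and Maf (0.74 ± 0.11) were among them. Of 24 genes of cholesterol and fatty acid synthesis, 5 fell (7 down and 1 up; 2e-05, and adjusted p = 0.0176 with an estimated correlation). Scd1 changed by -1.39 ± 0.18. Other rises were Zhx2 (4.54 ± 0.50), Rgcc (3.44 ± 0.24), Neb (1.81 ± 0.30), galectin gene Lgals3 (1.69 ± 0.21), Ccr4 (1.65 ± 0.27), Lama5 (1.59 ± 0.28) and Spp1 (1.39 ± 0.06). The myosin gene Myh7 had 1 count over the 4 knockout libraries against a mean of 42.3 CPM in the controls. Myh7, and Rgcc and Lgals3 among the rises, lie among the 200 tested genes nearest Irf9 on its chromosome. Other falls were Arl2bp (-2.42 ± 0.18), Cd74 (-2.32 ± 0.35), Ms4a4c (-1.75 ± 0.28), Dnahc8 (-1.60 ± 0.21) and Atrnl1 (-1.48 ± 0.26). Cd74 and H2-Aa (-2.97 ± 0.55) were the members that fell of 3 tested B cell markers (6.51e-08, and adjusted p = 0.0336 with an estimated correlation). Cd74 lay at 12.4 and 12.7 CPM in Irf9_KO 1 and 2 but at 0.75 and 0 in Irf9_KO 3 and 4. In all, 439 genes passed, 218 up and 221 down. Of other settings, 225 and 226 passed without Irf9_Ctrl 2 and 3, 196 with DESeq2 and 14 in the fit over all libraries. Pairs of libraries in each arm differed by little more than sampling noise, and 112 passed with such pairs summed into 1 sample (109 shared).

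Tbx21 encodes T-bet, the Th1 regulator. In its knockout most tested Th1 and effector genes fell, and 7 of 12 Th17 and 3 of 9 Th2 genes rose. None of these list calls held with an estimated correlation. Of 19 Th1 genes, 12 fell and 1 rose, the same adjusted over the list alone (camera adjusted p = 1.68e-26, and adjusted p = 0.276 with an estimated correlation). Without Tbx21 itself, 11 of 18 fell and 1 rose (7.25e-23, and adjusted p = 0.297 with an estimated correlation). Ifng changed by -9.57 ± 1.47, Nkg7 by -6.22 ± 0.25, Ccl3 by -5.83 ± 0.71 and Hlx by -4.70 ± 0.32. Of 12 effector genes, 9 fell and 1 rose (9 and 2 adjusted over the list alone; 5.36e-49, and adjusted p = 0.218 with an estimated correlation). Prf1 (-6.05 ± 0.34), Klrc1 (-5.94 ± 0.40), Ctsw (-4.75 ± 0.52), Klrk1 (-4.70 ± 0.40) and Gzmb (-4.70 ± 0.31) were among them. Of 4 tested CD8 T and NK cell markers, Klrd1 (-4.19 ± 0.52), also an effector list member, and Klre1 (0 counts in both knockout libraries, at least 4.03-fold lower) fell, and Cd8b1 (0.73 ± 0.22) and Eomes (0.44 ± 0.82) did not pass, or 2 down and 1 up adjusted over the list alone (0.02, and adjusted p = 0.36 with an estimated correlation). The list median was -1.88, or -0.787 with Klre1 set to its bound. Of 12 Th17 genes, 7 rose (7; 8.95e-07, and adjusted p = 0.36 with an estimated correlation). Il17f changed by 7.68 ± 1.23, Il17a by 5.79 ± 1.04 and Il22 by 4.91 ± 0.72. Of 9 Th2 genes, 3 rose (8 up and 1 down; 3.58e-06, and adjusted p = 0.36 with an estimated correlation): Gata3 (3.61 ± 0.73), Ccr4 (3.31 ± 0.42) and Il24 (2.35 ± 0.44). Of 19 Tr1 markers, 10 fell and 5 rose (12 and 6; 1.77e-05, and adjusted p = 0.276 with an estimated correlation). Prdm1 changed by -3.16 ± 0.38, Maf by -2.47 ± 0.18, Il21 by 2.01 ± 0.19 and Ahr by 1.94 ± 0.28. Of 51 interferon-stimulated genes, 18 rose (26 up and 2 down; 9e-12, and adjusted p = 0.36 with an estimated correlation). Isg15 changed by 2.60 ± 0.23 and Irf7 by 2.56 ± 0.39. Timd2 (7.43 ± 1.80), Mmp7 (6.79 ± 0.85), Il1rn (3.51 ± 0.71) and Fam177a, at least 40.9-fold higher than controls at 0, rose as well. In all, 738 genes passed, 328 up and 410 down. Of other settings, 221 passed in the fit over all libraries, 1710 and 1419 without Tbx21_KO 1 and 2, and 210 without Tbx21_Ctrl 1.

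Libraries labelled Atf3 knockout differed from controls in B cell, interferon and effector genes, while Atf3 itself was higher. Of 9 tested B cell markers, 8 rose and none fell, the same adjusted over the list alone (camera adjusted p = 7.16e-36, and adjusted p = 0.123 with an estimated correlation). H2-Aa and Cd79a were at 0 in the controls and at least 14.4-fold and 8.76-fold higher. Also, H2-Eb1 (3.71 ± 0.39) and Cd74 (3.47 ± 0.17) rose, with Mzb1 (4.42 ± 0.52), Wdfy4 (4.38 ± 0.46) and Syk (4.19 ± 0.37). The list median was 4.24, or 3.47 with genes at 0 set to their bound. The CD8 T cell genes Cd8a (-3.83 ± 0.27, 4.91 against 71 CPM) and Cd8b1 (-1.90 ± 0.23) fell. Cd8a was at 53.8 and 87.6 CPM of the library total in the 2 controls and at most 9.02 in any other library of the series. Whether CD8 T cells in these controls account for this fall, or for those of effector genes below, was not tested. Of 40 interferon-stimulated genes, 15 rose (18 up and 1 down adjusted over the list alone; 7.83e-12, and adjusted p = 0.156 with an estimated correlation). Iigp1 changed by 1.79 ± 0.19 and Ifi47 by 1.11 ± 0.12. Of 12 effector genes, 7 fell (9; 1.92e-12, and adjusted p = 0.197 with an estimated correlation), Serpinb9 (-1.51 ± 0.19), Klrc1 (-1.24 ± 0.21) and Prf1 (-0.93 ± 0.10) among them. Of 13 Tfh genes, 6 rose (7; 5.96e-12, and adjusted p = 0.196 with an estimated correlation). Cxcr5 changed by 2.59 ± 0.41 and Pou2af1 by 2.08 ± 0.14. Other falls were Batf3 (-2.64 ± 0.29), which lies beside Atf3 on its chromosome, Ccl9 (-2.61 ± 0.38), Il24 (-2.53 ± 0.31), Ptpn14 (-2.38 ± 0.24), Filip1 (-2.38 ± 0.33), Timp1 (-2.37 ± 0.19), Sytl3 (-2.17 ± 0.26), Tnfrsf8 (-2.03 ± 0.15) and Ifng (-1.15 ± 0.14). Eif3j1 (6.15 ± 0.87) and Wdfy1 (2.87 ± 0.27) rose. In all, 787 genes passed, 319 up and 468 down, with Xist at 0.251 against 191 CPM, Ddx3y at 32 against 0 and Nnt at 43.4 against 17.5. Further, 150 passed with DESeq2, 36 in the fit over all libraries and 376 without Atf3_KO 2.

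Ahr encodes the aryl hydrocarbon receptor, a ligand-activated factor. Of 18 tested cytokine genes, 5 fell and 1 rose (7 and 1 adjusted over the list alone; camera adjusted p = 6.06e-07, and adjusted p = 0.266 with an estimated correlation). Ifng (-1.36 ± 0.20), Spp1 (-1.11 ± 0.19), Ccl3 (-0.95 ± 0.16), Tnf (-0.92 ± 0.22) and Ccl4 (-0.88 ± 0.14) fell, and Ccl5 (1.22 ± 0.26) rose. Timp1 (-1.42 ± 0.24), Serpinb5 (-1.26 ± 0.27), Zfp277 (-1.10 ± 0.21) and Srp54b (-0.91 ± 0.17) fell too, the last pair near Ahr on its chromosome. Of 4 tested genes of the aryl hydrocarbon receptor battery, 1 fell (1; 0.00759, and adjusted p = 0.322 with an estimated correlation), the amino acid transporter gene Slc7a5 (-0.67 ± 0.10). Rises were Dynlt1b (1.35 ± 0.20), Asb2 (1.00 ± 0.18), the interferon-induced genes Ifi27l2a (0.92 ± 0.14) and Ifi27l1 (0.80 ± 0.17), Serpinb6b (0.61 ± 0.10) and Vps37b (0.59 ± 0.13). In all, 38 genes passed, 14 up and 24 down, including all 5 sex genes, with Xist at 0.913 against 555 CPM; 14 passed with DESeq2, 5 in the fit over all libraries, and 10 and 21 without Ahr_Ctrl 1 and 2.

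The Nfil3, Fosl2 and Cebpb comparisons gave few or no genes. Nfil3 itself had a mean of 103.6 CPM in its knockout libraries, with a standard deviation of 142, against 272.5 CPM in the controls. Most of its counts came from Nfil3_KO 1, so the Nfil3 comparison mixes libraries that differ in the targeted transcript. In Nfil3, Tgtp2 rose (2.00 ± 0.25) and Tgtp1, at 0 in both knockout libraries, was at least 36.6-fold lower; these are near-identical paralogs, so the split of reads between them is uncertain here and in every other comparison. No Nfil3 library could be dropped without moving this count of 2: it was 27 and 28 without Nfil3_KO 1 and 2, 1 without Nfil3_Ctrl 1 or 2 and 0 without Nfil3_Ctrl 3. Of 5 B cell markers in Nfil3 none passed over all genes, but 4 rose adjusted over the list alone (median 1.71; camera adjusted p = 1.39e-11, and adjusted p = 0.314 with an estimated correlation). Cd74 was at 108 CPM in Nfil3_KO 1 and 27.7 in Nfil3_KO 2, against 10.7 to 27 in the controls. In Fosl2, edgeR called 0 of 10816 genes, with 195 at an unadjusted p under 0.05, and DESeq2 called 12; 71 and 5239 passed without Fosl2_KO 1 and 2, and 1 without either control. In Fosl2_KO 1, the 20 most abundant genes held 94.1% of the counts. In Cebpb, edgeR called 0 of 765 tested genes, with 44 at an unadjusted p under 0.05, and DESeq2 called 0; 4 passed without either knockout library and 1 without Cebpb_Ctrl 1. These counts do not show that differences were absent.

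The knocked-out factors were also compared with each other's levels. Of 242 tests of a factor in another factor's knockout, 27 rose and 21 fell over all genes, and 35 rose and 37 fell adjusted over the list alone. These counts take the Atf3 comparison as labelled, which gave 3 of the rises (Irf1, Irf8 and Tbx21) and 2 of the falls (Prdm1 and Nfil3) over all genes; with its direction turned these would change sides. Maf fell in 5 and rose in 2 of its 14 tests, Prdm1 fell in 4 and rose in 3 of 14, and Nfil3 fell in 3 and rose in 3 of 16. Maf and Prdm1 rose in Ets1 (1.27 ± 0.10 and 1.42 ± 0.14) and Irf9 (0.74 ± 0.11 and 1.11 ± 0.15); in Irf4, Prdm1 rose (1.37 ± 0.19) and Maf fell (-1.32 ± 0.23). Ahr rose in 4 of 15 tests and fell in none: in Tbx21 (1.94 ± 0.28), Irf4 (1.66 ± 0.28), Irf9 (1.47 ± 0.40) and Ets1 (1.01 ± 0.19).

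Across comparisons, 141 of 351 list tests passed with the preset correlation and 27 with an estimated one over the 17 comparisons, and none passed for the interaction. With the targeted gene left out of its lists, 139 and 25 passed. The calls lost were the Tfh list in the double knockout, the STAT3 list in Nfil3 and, with an estimated correlation, Tr1 markers in Prdm1 and the double knockout. With it kept, Tr1 markers were called down in 8 and up in 3 (5 with an estimated correlation), STAT3 and IL-6 family targets down in 10 and up in 3 (3), and effector and cytotoxic genes down in 8 and up in 3 (3). Calls for glycolysis and hypoxia were down in 7 and up in 3 (2), and for the Th1 list down in 6 and up in 3 (1). The Th2 list was called down in 5 and up in 4 (2), cytokines and chemokines down in 5 and up in 3 (2), and interferon-stimulated genes down in 4 and up in 4 (2). The Treg list was called down in 3 and up in 4 (2), the B cell list down in 1 and up in 5 (3), cell cycle down in 3 and up in 4 (1) and cholesterol and fatty acid synthesis down in 1 and up in 1 (1). With an estimated correlation none of the following calls held: Th17 (4 down, 2 up), Tfh (3, 4), naive and memory (4, 1), co-inhibitory and co-stimulatory receptors (1, 2), aryl hydrocarbon receptor battery (2, 1), integrated stress (1, 2), myeloid and dendritic (2, 0), CD8 and NK (2, 2), immediate early and heat shock (0, 3) and sex genes (0, 4). The Atf3 comparison, taken as labelled, gave 8 of the calls down, effector and cytotoxic genes among them, and 6 of those up, which would change sides with its direction turned. In the experiments of 2 against 2 libraries the test with an estimated correlation had at most 2 degrees of freedom. A call lost there does not show that a list did not move. The erythroid and platelet list had 0 tested genes in every comparison.

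**Figure D4:**
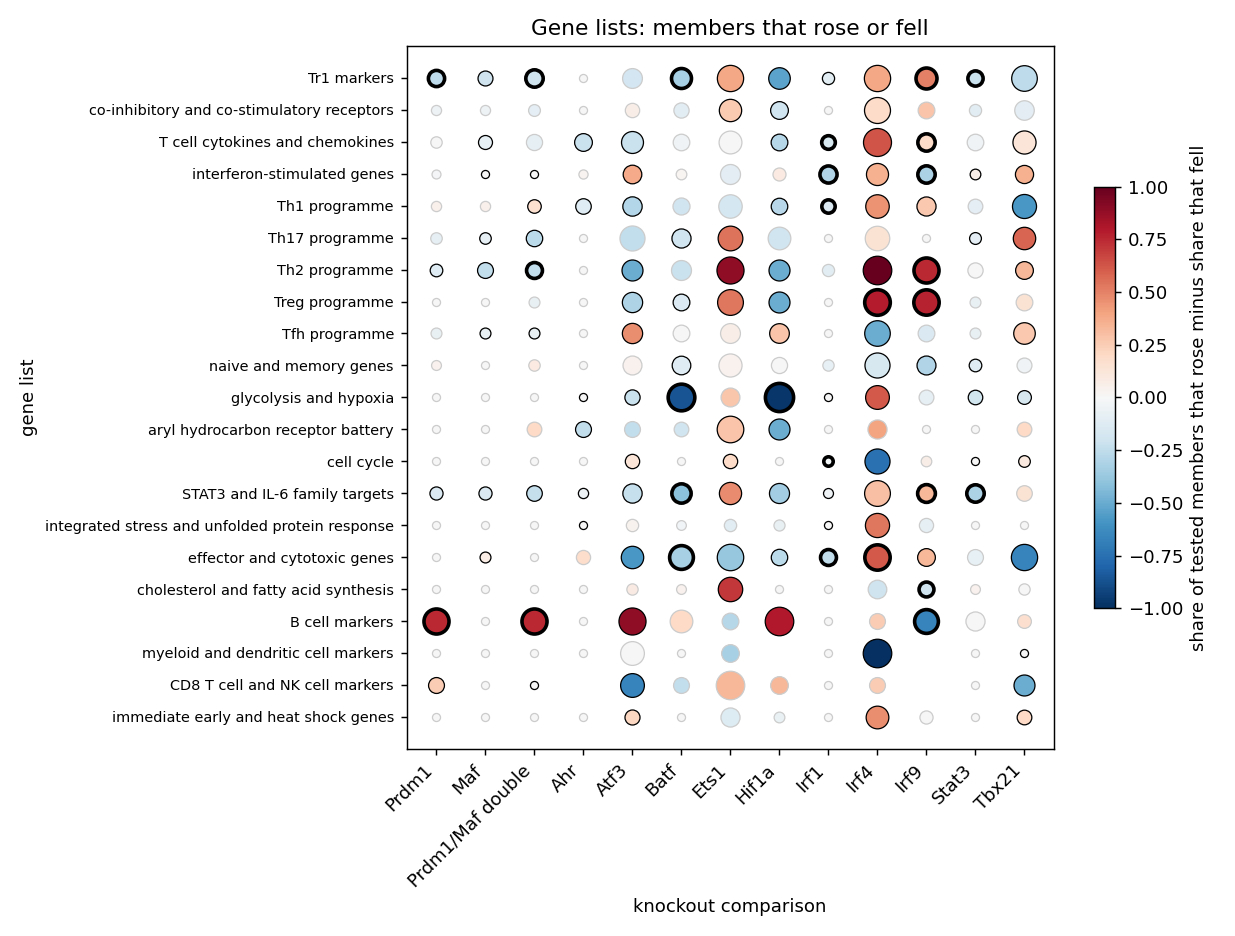
Gene lists (vertical) by knockout comparison (horizontal) for 13 comparisons; colour is the share of tested members that rose minus the share that fell, size the share that rose or fell, a black edge a camera adjusted p under 0.05 and a thick edge one that also holds with an estimated correlation. Glycolysis and hypoxia is the list with the largest share of falls in Hif1a, at 35 of 36, and Batf, at 31 of 36.

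Similarity of knockouts was measured as the correlation of log2 changes across genes, which are not independent replicates. Among pairs without shared controls it was highest for Batf and Hif1a (Pearson 0.492, Spearman 0.41, 9786 genes), where 188 genes fell in both against 12.6 if independent and 23 rose in both against 1.2. Dntt, Itga7, Il24, Slc2a3 and Bnip3 were among those named for both. Batf and Hif1a lie on the same chromosome, and Tgfb3, Pygl, Asb2, Serpina3f and Serpina3g were called near the target in both. Next came Atf3 and Hif1a (0.439), Hif1a and Stat3 (0.384), Ahr and Atf3 (0.348, but 0.0691 without sex genes) and Hif1a and Tbx21 (0.346). The sign of the values with Atf3 follows its labels, and with that direction turned both would be negative and leave this order. The pairs of the Prdm1 and Maf experiment, without replicate 3 of the double knockout, correlated at 0.755 (Prdm1 and double), 0.582 (Maf and double) and 0.478 (Prdm1 and Maf). Simulated groups without any effect against the same controls gave 0.474, 0.465 and 0.515. The covariances were 0.137, 0.106 and 0.0692 against simulated values of 0.025, 0.0247 and 0.0251, and 297 genes fell and 138 rose in both single knockouts.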

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

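No test in this part was chosen after its result was seen, apart from the fits without replicate 3 of the double knockout and with close library pairs summed. In the 4 Irf9 knockout libraries, 63 named genes were checked for a library far from the others. The gap of a library to its nearest was 0.851 of the group's whole range for Sc4mol in replicate 2. It was 1 for Myh7 in replicate 1, which rests on 1 count against 0 in the other libraries and does not show a library apart. Chance flags about 1 in 20 groups. The Irf9 comparison called 439 genes, and 1 of the 35 splits of its libraries gave as many, the real one. The highest of the others gave 63, with Irf9_KO 2, 3 and 4 in the control arm. If the libraries are separate samples, this share is under 0.05. Irf9_KO 1 and 2, Irf9_KO 3 and 4, and Irf9_Ctrl 2 and 3 differed by little more than sampling noise (chi-square per degree of freedom 1.22, 1.08 and 1.25). If such pairs are not separate samples, the splits cannot exclude chance. With close library pairs summed, 112 genes passed.

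The effect of losing Prdm1 differed with Maf present or absent for 23 genes by the interaction test. Of 40 draws of the group names over the libraries, the real one included, 15 gave as many, with 64 the highest of the others, so chance cannot be excluded. Without replicate 3 of the double knockout, 124 genes passed, and 3 of 40 splits gave as many, with 370 the highest of the others; a split with several times the real count points to a structure of the samples, but the draws mix 4 groups that differ among themselves, and what drives it was not tested. For the Prdm1 (83 genes, highest other split 9), Maf (64, highest other 8) and double knockout (166, highest other 64) comparisons, 1 of 10 splits gave as many genes in each, the real one, and 10 splits are too few for a share under 0.05.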

How the results depend on the processing

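The alternatives without replicate 3 of the double knockout (for Prdm1, Maf and the list tests), without Irf8_KO 1 (for Batf, Irf1 and Stat3), with close library pairs summed, and the list tests without the targeted gene, were chosen after seeing the data. Where no cause is given below, the cause was not tested. With DESeq2 size factors in edgeR, 127 genes were called in Prdm1 (83 up, 44 down), 281 in the double knockout (184 up, 97 down) and 37 for the interaction; other counts stayed within 1.5 times. With DESeq2, counts were 33 in Prdm1, 25 in Maf, 59 in the double knockout, 6 for the interaction, 14 in Ahr, 150 in Atf3, 1150 in Ets1, 12 in Fosl2, 331 in Hif1a, 101 in Irf1, 1462 in Irf4, 22 in Irf8, 196 in Irf9 and 299 in Stat3. With no filter on low counts, they were 21 in Prdm1, 12 in Maf, 67 in the double knockout, 13 for the interaction, 892 in Hif1a, 164 in Irf1, 41 in Irf8, 14 in Nfil3, 470 in Stat3 and 1178 in Tbx21. With a replicate block, they were 47 in Prdm1, 22 in Maf, 69 in the double knockout, 6 for the interaction, 1417 in Hif1a and 1783 in Tbx21. With 1 fit over all 69 libraries, which share 1 estimate of the spread, they were 19 in Prdm1, 16 in Maf, 88 in the double knockout, 11 for the interaction, 5 in Ahr, 36 in Atf3, 199 in Ets1, 351 in Fosl2, 143 in Hif1a, 307 in Irf4, 23 in Irf8, 14 in Irf9 and 221 in Tbx21. In Irf1, 13 passed with only the libraries of its own batches, and in Irf9, 112 with close pairs summed, which leaves fewer samples (2801 in Irf4, within 1.5 times).

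Leaving out 1 library at a time gave ranges of 37 to 1367 genes in Prdm1, 20 to 1021 in Maf, 53 to 2150 in the double knockout, 9 to 124 for the interaction, 10 to 54 in Ahr, 376 to 662 in Atf3, 118 to 434 in Batf, 0 to 4 in Cebpb, 1494 to 2556 in Ets1, 1 to 5239 in Fosl2, 301 to 1429 in Hif1a, 2 to 65 in Irf1, 1707 to 2857 in Irf4, 0 to 11 in Irf8, 225 to 419 in Irf9, 0 to 28 in Nfil3, 109 to 181 in Stat3 and 210 to 1710 in Tbx21. The highest values of Prdm1, Maf, the double knockout and the interaction are those without replicate 3 of the double knockout. Where this left 1 library in an arm, it was assumed to vary like the other groups; the single Stat3 knockout library could not be left out. Of the list tests, 141 passed with the preset correlation, 27 with an estimated one, 161 without replicate 3 of the double knockout and 139 with the targeted gene left out of its lists. The correlation of Batf and Hif1a was 0.492, 0.41 as Spearman's and 0.591 over genes called in either comparison.

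Il10 passed in 12 comparisons, adjusted over the list alone, and in 11 to 13 under the alternatives. Its call over all genes ended in Maf with no filter (-3.18), a replicate block (-3.17) or without any 1 Maf knockout library (-3.13 to -3.25), in Stat3 without the batch term (-3.47), in Irf1 with its own batches (-2.71) or without Irf1_Ctrl 2 (-2.14), in Atf3 with DESeq2 (-0.76) and in Atf3 (-0.75), Hif1a (-1.50) and Irf9 (0.84) in the fit over all libraries. It passed in Tbx21 with no filter (-1.81), a block (-1.94), the fit over all libraries (-1.80) and without Tbx21_KO 1 (-1.06), Tbx21_KO 2 (-3.41) or Tbx21_Ctrl 1 (-2.27). It also passed in Fosl2 without Fosl2_KO 2 (adjusted p = 0.0313), where the remaining knockout library had 0 counts of Il10, so that its fitted change is no measure of size. The Maf fits that lost the call kept replicate 3 of the double knockout. Without that library Il10 in Maf passed (-3.18, adjusted p = 6.62e-13). No called value changed sign. Values that had not passed did so for Irf8 without LinkedA_Ctrl 1 or Irf8_KO 1 (range -0.24 to 0.52 over libraries left out), for Fosl2 without Fosl2_KO 1 (-0.043 to 1.61), and for Il10 in Cebpb without Cebpb_KO 1 or Cebpb_Ctrl 2 (-3.14 to 0.92) and in Nfil3 without Nfil3_KO 2 (-0.65 to 0.17). Over 702 named gene values and all alternatives, 5807 of 7225 values kept direction and side of the threshold, 1397 fell below it, 15 rose past it and 6 changed sign. Of those that fell below it, 370 did so in the fit over all libraries, 147 with DESeq2 and 689 when a library was left out. Depth limits Cebpb, with 30593 to 46232 counts per library. In Fosl2 the spread between libraries was wide (common coefficient of variation 0.532), Rn45s held 84.8% of the counts of Fosl2_KO 1, and the check on simulated data recovered 5.38% of changes with a log2 of 2. The median change of all genes in Fosl2 was -0.16, that of the double knockout -0.30 and that of the interaction -0.34.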

Other observations

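The tests on genes near Ahr, on the sex of the animals in Ahr and on RNA from B cells and other cell types were chosen after results were seen. Several gene groups moved beyond those described above. In the Irf4 comparison, 22 of 48 interferon-stimulated genes rose and 5 fell (25 and 7 adjusted over the list alone; camera adjusted p = 2.09e-05, and adjusted p = 0.071 with an estimated correlation), with Ifit1 at 3.79 ± 0.32 and Gbp5 at -1.24 ± 0.11. Of 36 genes of glycolysis and hypoxia, 23 rose and 1 fell (24 and 1 adjusted over the list alone; 9.9e-09, and adjusted p = 0.2 with an estimated correlation), with Bnip3 at 1.09 ± 0.11. Of 26 genes of the integrated stress and unfolded protein response, 16 rose and 2 fell, the same adjusted over the list alone (9.38e-06, and adjusted p = 0.155 with an estimated correlation); Trib3 changed by 1.17 ± 0.13 and the chaperone gene Hspa5 by 0.98 ± 0.09. In the Batf comparison, 6 of 24 naive and memory genes fell and 3 rose (10 and 4 adjusted over the list alone; 0.00661, and adjusted p = 0.121 with an estimated correlation), with Satb1 at -1.87 ± 0.25 and Id3 at 2.47 ± 0.39. In the Ets1 comparison, Ahr rose (1.01 ± 0.19), and of 7 genes of the aryl hydrocarbon receptor battery 4 rose and 2 fell (4 and 3 adjusted over the list alone; 0.00302, and adjusted p = 0.244 with an estimated correlation), with Ahrr at 1.78 ± 0.40 and Nfe2l2 at -0.64 ± 0.15. Cd74 rose in Batf (2.19 ± 0.24), Stat3 (1.69 ± 0.32) and Tbx21 (1.52 ± 0.18) and fell in Ets1 (-0.74 ± 0.16).

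Nnt, which lacks several exons in the C57BL/6J substrain, was higher in libraries labelled knockout for Atf3 (40.6 and 45.9 against 16 and 18.9 CPM of the library total), Irf4 (34.9 and 36.3 against 14.2 to 17.8), Ets1 (52.2 and 56.1 against 32.8 and 40.1) and Maf (53.1 to 55.6 against 16.6 to 19.7). It was also higher, without passing, in Batf (30.8 and 34.4 against 11.3 to 16.7; adjusted p = 0.189), Irf8 (22.7 and 30.1 against 11.3 to 16.7; 0.891), Stat3 (41.6 against 12.6 and 16.7; 0.143), Nfil3 (34.4 and 41.8 against 13.6 to 33.6; 1) and Tbx21 (17.5 and 19.3 against 12.8 and 14; 0.365). In Irf1 it was lower, without passing (3.46 to 8.11 against 11.3 and 15.6; adjusted p = 0.592). Elsewhere the arms overlapped, as in Hif1a (25.1 and 25.8 against 45 and 21.4, adjusted p = 0.537), and in Cebpb it had 0 counts. Replicates 1 and 2 of the double knockout lay at 20 and 18.7 CPM, near the controls shared with Maf. The rise in Maf was thus not shared by both groups that lack Maf. By Xist and Ddx3y, the knockout-labelled libraries of Ahr, Atf3, Ets1 and Irf4 came from male and their controls from female animals. Those of Nfil3 were mixed, and Prdm1 and Maf libraries were male apart from replicate 3 of the double knockout, which had 0 counts of both genes.

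Genes near a deleted locus can stay linked to it when a mutation is bred onto another background. Of the 200 tested genes nearest Ahr, 2 were called (Zfp277 and Srp54b), a share 3.14 times that elsewhere (exact one-sided Fisher p = 0.142). A segment linked to the locus may account for them, and so may the sex of the animals, for which this same ratio of 3.14 was the test: 2 genes are too few to decide either. In 1 of 11 other comparisons, Irf1, called genes were more frequent near the target, with a ratio of 9.61 (exact adjusted p = 5.45e-05). Igtp, Irgm2, Ifi47, Tgtp1, Tgtp2 and Irgm1 lie there and are interferon-induced, so that linkage and regulation cannot be told apart for Irf1. In the remaining comparisons a share over 200 genes cannot exclude a shorter linked segment. The ratio in Batf was 1.75 (exact one-sided Fisher p = 0.0329, adjusted p = 0.197). Hif1a was among the 14 called genes near Batf, so its fall in Batf may be linkage or regulation. Batf3, which lies beside Atf3, fell in the Atf3 comparison. Other named genes among the 200 nearest their target included Ptpn14 (Atf3), Sgk1 (Prdm1), Tgfb3 (Hif1a), Igfbp4 (Stat3) and Myh7, Rgcc and Lgals3 (Irf9). Whether linkage accounts for any of them was not tested gene by gene.

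B cell markers were higher in libraries labelled knockout for Hif1a and Atf3, with Cd74 at 163 and 266 against 23.1 and 30 CPM and at 163 and 166 against 11.2 and 18.4 CPM. In Atf3, 8 of 9 tested markers rose and none fell, and in Hif1a 9 of 10 rose and H2-Ab1 fell (-0.99 ± 0.19). The bounds for RNA from B cells were set after these counts were seen, so the counts do not support it, and as no value excludes it either, it stays open in both. RNA from many other cell types in Hif1a was tested on the CD8 and NK list (adjusted p = 0.23, with Cd8a at 3.02 ± 0.60), as the myeloid list had 2 tested genes; the bound set against it was a p over the threshold, which was wrong, since 3 tested genes that miss it decide nothing. The labels name naive CD4 T cells and no sort, activated T cells also express some of these genes, and an effect of the deletions was not tested. RNA from CD8 T cells in the Atf3 controls, where Cd8a was at 53.8 and 87.6 CPM of the library total, was not tested either.

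Sex differed between the arms of Atf3, Ets1 and Irf4 as it did in Ahr, where the labelled Ahr knockout cannot be separated from it. Over the called autosomal genes, the slope of the Ahr change on that of each comparison was 0.0716 in Atf3 (95% interval 0.049 to 0.0943), -0.00928 in Ets1 (-0.0208 to 0.00223) and -0.0142 in Irf4 (-0.0231 to -0.00524). These intervals take genes as independent, so they measure the spread over genes and not that between libraries. The small slopes themselves argue against a sex difference of the size seen in Ahr as the whole cause of the changes. A smaller share of them, and a sex difference that acts otherwise in each experiment, stay open as untested.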
